A study of Mus musculus with 20 samples.

How the data were processed

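RNA-seq was done on mouse male germ cells at 4 stages (meiotic cells, round spermatids, elongating spermatids and mature sperm) of 3 backgrounds: SV129E wild type, Gcn5 control and Gcn5 conditional knockout (Gcn5 cKO). Per the labels' protocols, testis cells were separated into fractions by sedimentation at unit gravity. A purity of at least 85% was recorded for the SV129E fractions only. Sperm were taken from the cauda epididymis and treated with a somatic cell lysis buffer. Total RNA was depleted of ribosomal RNA, made into ScriptSeq libraries and sequenced as single reads of 75 cycles. Groups came from the sample titles, and replicate numbers from the same titles. The 20 libraries make 12 groups, with 2 libraries in each of the 8 Gcn5 groups and 1 in each of the 4 SV129E groups.

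The deposited count table held whole, unnormalised counts per gene symbol in 1 column per library, and every column matched a library by name (columns of no sample: 0). Per the submitters' processing notes, TopHat2 2.0.11, HTSeq 0.6.1p1 and the mm9 build were used; the annotation, the filters and whether counting used strand are not given in the sources used here. Where counting did not use strand, reads of a gene and of an antisense or overlapping partner cannot be told apart, and counts of genes with near-identical copies can be split or dropped. The table had 24421 genes and 1 entry for reads of no gene, which was left out of library sizes and tests. It held 1.37 to 15.96% of all counts in the Gcn5 libraries and 0.00653 to 0.0186% in SV129E, a difference whose origin is not given in the sources used here. No 2 libraries were identical (0 pairs).

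The second deposited table held FPKM values of 24205 genes, adjusted to spike-in RNA by the authors per the file name and labels, with 1 pooled column per background and stage. How the authors derived the factors is not given in the sources used here. In 11 of the 12 columns the FPKM values were exact weighted sums of the library counts with a single weight per library, within a relative tolerance of 1e-4. Among the 11, the SV129E meiotic column matched by construction, since the length term of each gene was taken from it. Each library's own adjusted FPKM was recovered from its counts and weight, taking a pooled column as the mean over its libraries. The exception to a single weight was cKO elongating replicate 1. Its contribution separated into 2 parts with weights of 0.184 and 0.323, each whole within 0.02 counts for 100% of genes. The gene counts of the 2 parts differed by more than sampling noise (chi-square per degree of freedom 45.2; Spearman's rho across genes 0.980). The parts were used together as 1 library, and each alone as an alternative. The test of the spike-in adjusted level, designed for library values, used these recovered values on the log2(FPKM + 1) scale, where folds of low genes are understated.

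Differential expression was computed with edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3 on the counts as deposited, with TMM factors (0.524 to 1.78), genes kept by filterByExpr on the groups, and Benjamini-Hochberg adjusted p below 0.05. The 16 Gcn5 libraries were fitted together as 8 group means (17765 genes, 8 residual degrees of freedom, biological coefficient of variation 0.294), which gave the genotype contrasts, their average, the genotype by stage interaction and the stage contrasts of the controls. SV129E was compared with the Gcn5 controls in an additive model of stage and background (18011 genes, 7 residual degrees of freedom). Standard errors are the log2 change divided by the square root of F. Control and knockout libraries of the same stage and replicate number deviated together from their group means, with a correlation of the deviations across genes of 0.508, 0.517 and 0.312 in meiotic cells, round and elongating spermatids and weakly, at 0.103, in sperm, although the labels do not say what a replicate number marks. The fit fixed beforehand has no term for it, and values with the replicate number as a block are given where they change a call or a count. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were alternatives. Summary tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

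The design, most alternatives and 24 gene lists were fixed before the data were examined, and alternatives added later are named as such in the closing section. Lists were tested with limma's camera on voom values with a preset correlation of 0.01, adjusted over all lists and contrasts of the same family (genotype or stage), and again with an estimated correlation. The list of mitochondrially encoded genes had 0 members in the count table and gave no result. Lists that marked other cells which fractions or sperm pellets can hold were spermatogonia, Sertoli, Leydig, myoid and stromal, endothelial, blood and immune cells, and epididymal epithelium. Genes were named by a rule: per contrast the 12 largest rises and 12 largest falls among genes past the threshold with at least 5 CPM in the higher group and no overlap between the libraries of the groups (for the average and SV129E, the same sign in all 4 stages), or, where fewer passed, those that did and the 5 with the smallest p-value; 12 genes for the interaction; up to 4 members of each list; and always Kat2a, Kat2b, Prm1, Prm2, Tnp1, Tnp2 and Brdt. Predicted genes, small RNAs and pseudogenes were counted but not named. Only part of the genes so chosen are described. Dhx58 and the Y- and X-linked genes as groups were singled out after their values were seen.

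A count of 0 was taken to allow 3 counts, which stood for 0.0909 to 13.6 CPM over the libraries. Folds against a group without counts were computed against 3 counts over the group, and ratios against 1 to 3 counts carry a 95% interval; both cover counting error only. Chromosome membership (24337 genes, 99.7%), gene order, shared sequence of 31 bases and exon overlap came from GENCODE M21 on GRCm38, matched by symbol. Gene order and exon overlap rest on its positions, whereas the counts were made on mm9.

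The scripts were tested on simulated data with the real library sizes and spread per gene. For genotype and SV129E the means were those of the controls per stage. For the stage steps every group had the means of control meiotic cells, so sperm means did not enter. Changed genes were drawn above a low limit of expression, and libraries of the same replicate number did not move together, unlike real ones. In edgeR's test 2-fold and 4-fold changes were recovered in 5 and 67.7% of the changed genes in the meiotic contrast, 5 and 60.6% in the round spermatid contrast, 5 and 54.5% in the elongating spermatid contrast, 0 and 11.1% in the sperm contrast, and 56 and 83.8% in the average (17102 genes). They were recovered in 4.21 and 62.1% from meiotic cells to round spermatids, 0 and 55.8% from round to elongating spermatids and 0 and 35.8% from elongating spermatids to sperm (14818 genes), and in 19 and 84% for SV129E (17505 genes). Camera called 5 of 5 lists that were moved and 0 of 20 that were not, in simulated genes drawn independently of each other, unlike real ones. Alternatives were other scalings (RLE, upper-quartile, library size alone, spike-in weights), low-count filters, tests, sets of libraries, a term for the replicate number (the replicate block), and leaving out each library in turn; spike-in transcripts were not among the genes counted, so that scaling by their totals was not run.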

Results

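RNA was profiled in mouse male germ cells at 4 points of their development: meiotic cells, round spermatids, elongating spermatids and mature sperm. The 20 libraries fell into 12 groups. For each stage there were 2 libraries of Gcn5 control mice, 2 of mice with a germ-line conditional knockout of Gcn5 (Gcn5 cKO), and 1 of SV129E wild-type mice. Gcn5 is the older name of Kat2a, a histone acetyltransferase that is the catalytic subunit of the SAGA and ATAC complexes. The sample labels call the controls wild type on C57BL6, whereas the treatment protocol describes controls with 1 floxed allele, and knockouts carrying a floxed and a deleted allele with Cre recombinase under the Stra8 promoter. Meiotic cells and spermatids came from sedimentation fractions, and sperm from the cauda epididymis after lysis of somatic cells. A purity of at least 85% was recorded for the SV129E fractions and none for the Gcn5 fractions. Each SV129E collection pooled 11 mice. Nothing in the labels says that the replicates of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

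Depth differed most between sperm and the other stages. Counts assigned to genes ranged from 6947707 to 33013551 in the meiotic and spermatid libraries and from 221290 to 2020331 in the sperm libraries. In sperm 3 counts, the limit that a count of 0 allows, stood for 1.48 to 13.6 CPM. The ribosomal RNA precursor gene Rn45s took 8.53 to 28.1% of gene counts in sperm and at most 2.15% elsewhere. Among replicate pairs, the counts of every pair differed by more than sampling noise (chi-square per degree of freedom 15.7 to 67.1), and the log2 CPM of the control elongating pair correlated least outside sperm (Pearson's r across genes 0.919, with 21451 genes detected in replicate 2 and 17082 in replicate 1). Each pair was compared over its own set of genes with enough counts, 9420 in the control elongating pair. Intervals and limits of detection cover counting error only.

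The targeted gene was examined first. Kat2a was at 27.1 and 14.6 CPM in the 2 control meiotic libraries and at 15.5 and 9.76 CPM in the 2 knockout libraries, so that the ranges overlapped in this stage. In round spermatids Kat2a was at 15.3 and 6.45 CPM in controls and 3.21 and 2.09 CPM in knockouts, in elongating spermatids at 4.61 and 3.24 CPM against 3.04 and 2.19 CPM, and in sperm at 22.4 and 15.5 CPM against 9.26 and 2.81 CPM. Averaged over the stages, Kat2a fell by 1.18 on the log2 scale (SE 0.26; edgeR quasi-likelihood test, adjusted p = 0.0496). The call was at the threshold: it held in 8 of 33 alternative settings, whose adjusted p ran from 0.00046 to 0.429, and the log2 change was negative in each of them. Kat2a was lower in the knockout library in 8 of 8 pairs of the same stage and replicate number. With the replicate number as a block its adjusted p was 0.00046 in the average and 0.00580 in round spermatids (log2 change -1.98). SV129E libraries held 23.5, 10.3, 6.26 and 21.0 CPM of Kat2a in the order of the stages. The counts cover the whole gene model, and the deleted exons are not named in the sources used here. Kat2b, the paralogous acetyltransferase, was not called in the average.

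**Figure D1:**
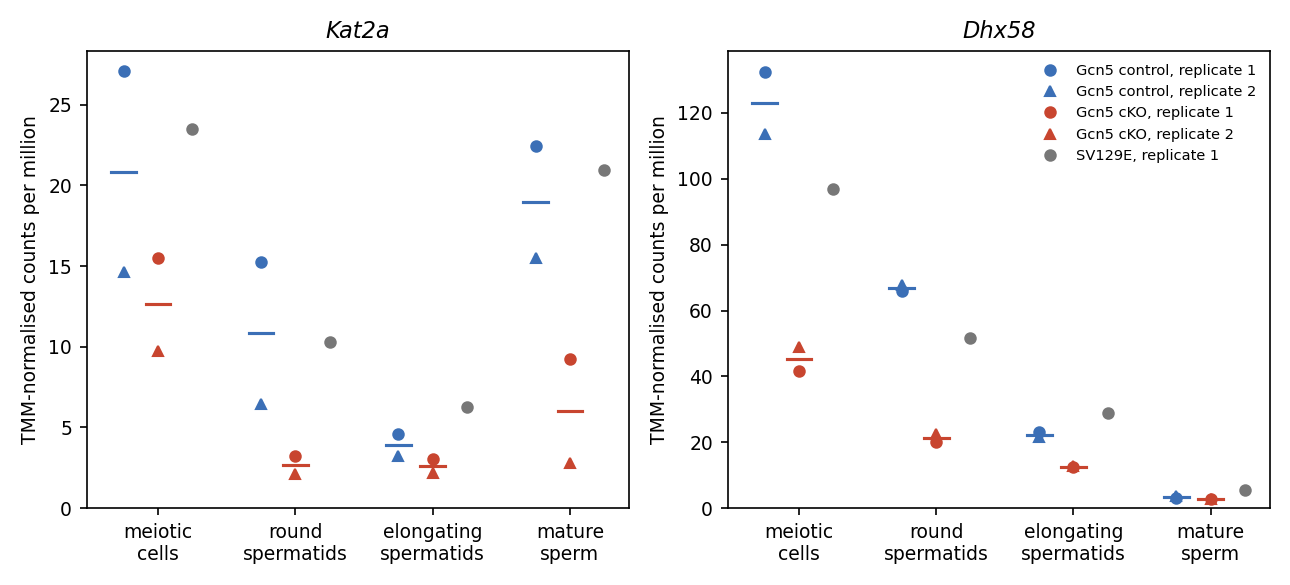
TMM-normalised CPM (vertical axis, linear) of Kat2a and of its neighbouring gene Dhx58 at each stage (horizontal axis); each point is a library, bars are means of 2 libraries, and SV129E has 1 library per stage. Kat2a was at 3.21 and 2.09 CPM in the knockout round spermatids against 15.3 and 6.45 CPM in the controls, and the ranges overlapped in meiotic cells.

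The genotype difference was tested over all stages at once, as the mean of the 4 stage contrasts. Of 17765 genes, 97 were higher and 12 lower in Gcn5 cKO libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Of the 97 higher genes, 36 were X-linked and 11 Y-linked. Genes and list members named for the average are not set apart by chromosome. The higher genes included Hsd3b1, which makes steroid hormone precursors (log2 change 2.51, SE 0.42, 5.70-fold, adjusted p = 0.0147), Nptx2, a neuronal pentraxin (2.70, SE 0.27, 6.50-fold), the surface antigen Cd52 (1.94, SE 0.40), the matrix proteoglycan Dcn (1.91, SE 0.37) and the collagen chain Col6a1 (1.80, SE 0.36). Beside Kat2a, the lower genes were led by Sntg1 (log2 change -1.64, SE 0.36), Gtf2ird2 (-1.45, SE 0.30), Elfn1 (-1.12, SE 0.24), Pnma2 (-1.12, SE 0.21) and Dhx58, an RNA sensor of the RIG-I family (-1.05, SE 0.19, 2.07-fold). They were followed by Pitpnb (-1.03, SE 0.22), Dcbld2 (-0.96, SE 0.20), Mroh2a (-0.70, SE 0.15) and Rfx3, a transcription factor of ciliated cells (-0.66, SE 0.13). A further 7 of the genes with the largest rises had no count in control sperm, so their fitted average depends on the prior count. Their log2 changes with mature sperm left out were 1.80 (SE 0.33) for the methyltransferase Bhmt, 1.84 (SE 0.30) for the adhesion molecule Vcam1, 1.34 (SE 0.24) for the laminin chain Lamc3, 1.30 (SE 0.16) for Fam122c and 1.30 (SE 0.26) for the RNA-binding stem cell factor Lin28a, each still past the threshold. In that fit Taf9b (0.58, SE 0.16, adjusted p = 0.0701) and Mpped1 (0.46, SE 0.16, adjusted p = 0.123) were not. Of the lower genes Sntg1 (-1.57, adjusted p = 0.0554), Pnma2 (-0.67, 0.0635), Pitpnb (-0.74, 0.0752), Dcbld2 (-0.48, 0.0884) and Rfx3 (-0.32, 0.124) did not pass in that fit either. For 4 other genes a group entering the average held 1 to 3 counts. In sperm the ratio of CPM was 12.8-fold for Nptx2 (95% counting interval 4.14 to 64.0), 2.95-fold for Hsd3b1 (0.292 to 145) and 4.52-fold lower for Elfn1 (1.16 to 25.5). For Cd52 in elongating spermatids it was 6.40-fold (2.07 to 32.0).

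The size of this set depended on the libraries and the method. With the replicate number as a block 599 genes were called (480 higher, 119 lower), the 109 among them. Nptx2 kept its call in 33 of 33 alternative settings, Hsd3b1 and Fam122c in 32, Dhx58 in 20, Cd52 in 17, Gtf2ird2 in 16, Sntg1 in 11 and Elfn1 in 10. With replicate number 1 alone and stage as a term 163 genes were called (143 higher, 20 lower), and with replicate number 2 alone 108 (99 higher, 9 lower), each sharing 52 genes with the 109. The replicate numbers were also taken as batches because the share of counts assigned to no gene was higher in replicate 2 than in replicate 1 in 8 of 8 groups. Within a single stage a batch holds 1 library per group. Leaving out 1 library gave 20 genes without cKO sperm replicate 1, 33 without cKO meiotic replicate 2 or cKO elongating replicate 2, and 35 and 67 without cKO round replicate 2 and 1. It also gave 41 and 54 without control round replicate 1 and 2, 58 without cKO meiotic replicate 1, and 66 without control meiotic replicate 1. Higher counts were 197 without cKO sperm replicate 2, 203 without control sperm replicate 2 and 205 without control elongating replicate 1. With the mature sperm libraries left out there were 708 genes (551 higher, 157 lower), 94 of them among the 109. Scaling by library size alone moved the median log2 change of all genes in the average from 0.02 to 0.15, and spike-in scaling moved it to 0.44, with 0.17, 0.41, 0.68 and 0.42 in the 4 stages in order.

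Fixed lists of genes were tested as sets with limma's camera (preset correlation 0.01). In the average over stages, the Leydig cell list, genes of the steroid-producing cells between the tubules, was higher in Gcn5 cKO libraries (adjusted p = 2.86e-08). Of its 22 measured members 3 rose, Hsd3b1, Akr1cl (log2 change 1.72, SE 0.33) and Aldh1a1 (1.38, SE 0.27), none fell and the others did not pass, with 8 higher and 1 lower when adjusted over the list alone. The myoid and stromal list was also higher (2.07e-07), with Pdgfra, a growth factor receptor (1.73, SE 0.21), and Dcn past the threshold out of 23 members, and 7 adjusted over the list alone. The immediate early genes were higher (1.25e-06), with Btg2 (1.16, SE 0.22), Egr2 (1.75, SE 0.37) and Klf6 (1.37, SE 0.29) past the threshold out of 24, and 11 adjusted over the list alone. In the spermatogonial list (4.41e-05) Lin28a rose out of 24 members, with 3 adjusted over the list alone. The macrophage lysozyme Lyz2 (2.16, SE 0.39) rose out of 19 members of the endothelial, blood and immune list (0.000144), with 5 adjusted over the list alone. The actin-related Actrt1 (1.34, SE 0.28) rose out of 45 members of the elongating spermatid list (0.0447), with 5 adjusted over the list alone. The Sertoli cell (0.0376), interferon (0.0408) and p53 and apoptosis (0.0424) lists were higher with 0, 0 and 1 members past the edgeR threshold over all genes, and 0, 3 and 2 adjusted over the list alone. The calls of all these lists were lost with an estimated correlation, where the lowest adjusted p was 0.146, for the Leydig list. Single libraries also ended the calls of the elongating spermatid list (7 libraries, adjusted p up to 0.765 without cKO sperm replicate 1) and the Sertoli list (8, up to 0.164 without control meiotic replicate 2). They did so for the interferon list (8, up to 0.398 without control round replicate 1) and the p53 list (3, up to 0.0795 without cKO sperm replicate 1; 0.0525 with the replicate block). The Leydig, myoid, immediate early, spermatogonial and immune lists kept theirs when any 1 of the 16 libraries was left out. In other splits of the libraries within stages, however, the same test called a median of 7 lists and up to 12. The real split gave 11 when adjusted within the average alone, so chance was not excluded for their number. No such splits were run for lists in single stages. More of the marked cells in the knockout fractions would also raise their lists and single genes. This was not told apart from changes in germ cells. The elongating spermatid list was not called without mature sperm (0.417), nor the Sertoli (0.11) and interferon (0.0839) lists with spike-in scaling.

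Among lists tied to the Gcn5 complexes and to chromatin remodelling, the SAGA and ATAC subunits were lower as a set (camera, adjusted p = 0.0484, median log2 change -0.15, or -0.08 with genes that had no count in a group at their bound; adjusted p = 0.368 with an estimated correlation). Of 33 subunits, Kat2a fell and Taf9b, a TATA-binding protein associated factor, rose. When adjusted over the list alone 2 were higher and 5 lower, among them Taf6l (-0.59, SE 0.17). With mature sperm left out Taf9b did not pass in edgeR (log2 change 0.58, adjusted p = 0.0701). Members of the list were not set apart by chromosome, and the median log2 change of X-linked genes in the average was 0.63. The set holds the targeted gene Kat2a and was not tested without it. The call ended when any 1 of 9 libraries was left out (adjusted p up to 0.184, without control elongating replicate 1), without mature sperm (0.438) and with spike-in scaling (0.229). Lists not called in the average were other acetyltransferases (adjusted p = 0.40), deacetylases (0.786), histone variants of spermatids (0.928), protamines and transition proteins (0.436), meiotic prophase (0.787), round spermatid (0.750), axoneme and flagellum (0.0710), sperm glycolysis (0.0508), piRNA pathway (0.0710), epididymal epithelium (0.849), ribosomal proteins (0.972), proteasome (0.655) and unfolded protein response (0.717). None of the members of these lists passed over all genes in edgeR's average contrast, whereas with the replicate block the protamine gene Prm1 did (log2 change 0.58, adjusted p = 0.0450). The protamine genes Prm1 and Prm2, which package sperm DNA, stood at 43354 ± 14914 and 39982 ± 8869 CPM in knockout elongating spermatids (SD, n = 2) and at 32182 ± 22183 and 35166 ± 8385 CPM in the controls (SD, n = 2), differences smaller than the replicate SDs. In pairs of the same replicate number the knockout library was higher in 2 of 2 for either gene, with Prm2 at 46253 against 41095 and at 33710 against 29237 CPM. With the replicate block neither Prm1 (adjusted p = 0.501) nor Prm2 (0.886) was called in this stage, and the fitted change of both turned negative without control elongating replicate 2.

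**Figure D2:**
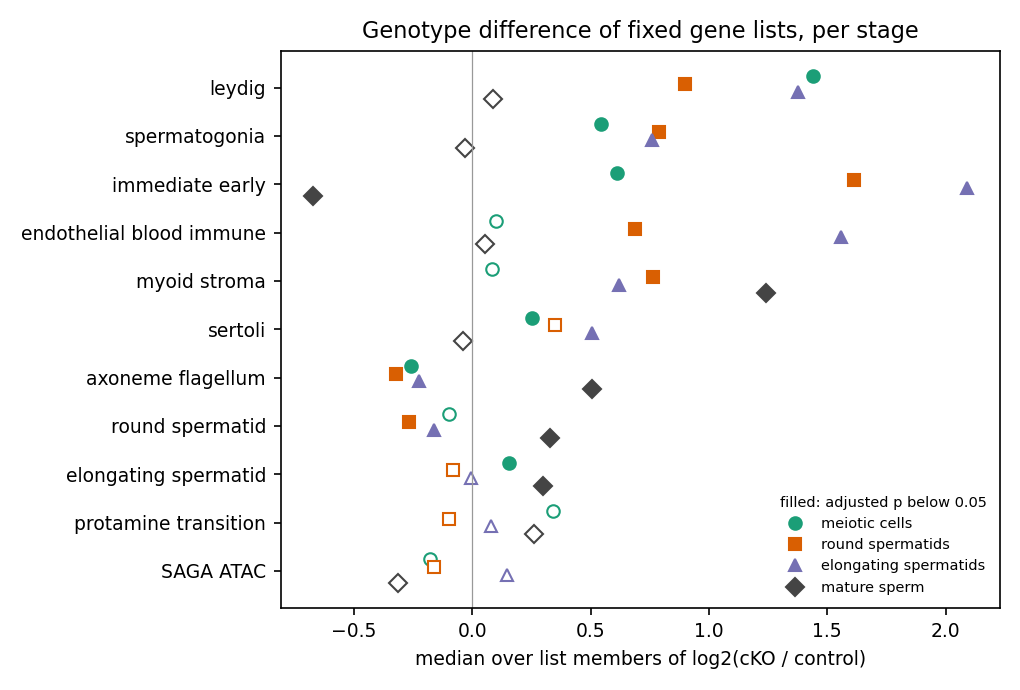
Median over the members of each fixed gene list (vertical axis) of the log2 change between Gcn5 cKO and control libraries (horizontal axis), per stage; filled symbols have a camera adjusted p below 0.05 with the preset correlation. The Leydig list had medians of 1.44, 0.90 (0.80 with genes without a count in a group at their bound) and 1.38 in meiotic cells, round and elongating spermatids and 0.09 (0 at their bound) in mature sperm.

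Genes of the sex chromosomes were higher in Gcn5 cKO libraries than in controls. The median log2 change over 735 X-linked genes was 0.71 in meiotic cells, 0.66 in round spermatids, 0.50 in elongating spermatids and 0.29 in sperm. Over 30 Y-linked genes it was 1.32, 1.09, 0.78 and 1.06, and over 16962 autosomal genes -0.07, -0.08, 0.03 and 0. Of the 97 genes that rose in the average 36 were X-linked and 11 Y-linked, out of 765 sex-linked genes among the 17765 tested. Setting the median log2 CPM of X-linked genes against that of autosomal genes in each library, the knockout libraries lay above the controls by 0.52 on average, with each knockout library above both controls in 4 of 4 stages (exact permutation test within stages, two-sided, p = 0.00154, the smallest it can give). In sperm this rests on a value of 0 in cKO sperm replicate 2, a shallow library in which both medians fell on the same whole count. Without sperm the difference was 0.49 (exact permutation p = 0.00926, the smallest it can give). Over pairs of the same stage and replicate number the knockout library was higher in 8 of 8. Leaving out the pair of that sperm library it was higher in 7 of 7, by 0.46 (exact permutation of signs, p = 0.0156, the smallest it can give). The X-linked median of the average contrast lay 0.63 above the autosomal one, 0.67 within replicate number 1 and 0.65 within replicate number 2, and 0.07 above it on the compressed log2(FPKM + 1) scale. These tests take the 4 stages as separate, yet differences between replicates also correlated across stages of a genotype (0.510 in controls and 0.496 in knockouts between meiotic cells and round spermatids). If the fractions of a replicate number share a preparation, 2 units per genotype remain, for which no exact test can pass the threshold, and this holds for the spike-in adjusted level too. The grouping by chromosome was chosen after the data were seen.

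**Figure D3:**
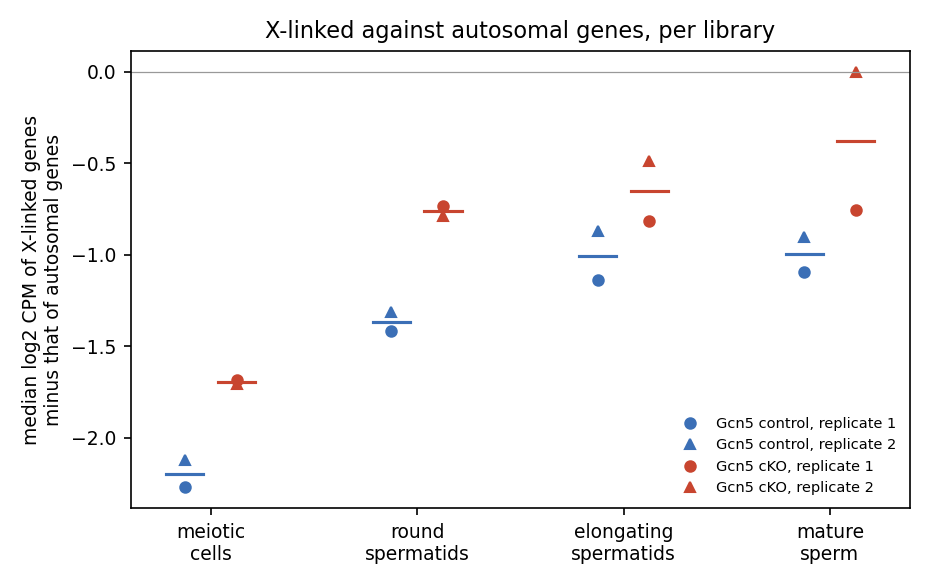
Median log2(CPM + 0.5) of X-linked genes minus that of autosomal genes (vertical axis) in each Gcn5 control and cKO library by stage (horizontal axis). Control meiotic cells were at -2.27 and -2.12 and knockout meiotic cells at -1.68 and -1.71; the value of 0 in cKO sperm replicate 2 comes from a shallow library in which both medians fell on the same whole count.

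In meiotic cells the Leydig list stood furthest from the other genes. It was higher in Gcn5 cKO libraries (camera, adjusted p = 1.24e-22, and 0.0309 with an estimated correlation), with a median log2 change of 1.44. When adjusted over the list alone 11 of its 22 members were higher. Among them were Hsd3b1 (2.54, SE 0.43), the fatty acid binding protein Fabp3 (2.16, SE 0.47) and the steroid hydroxylase Cyp17a1 (1.68, SE 0.47). The summed CPM of the list was 354 and 444 in knockout and 168 and 133 in control libraries. Spermatogonial genes were higher as a set (adjusted p = 2.06e-08; 0.157 with an estimated correlation; median 0.54), with Kit at 1.15 (SE 0.40) and Zbtb16 at 1.59 (SE 0.60). Immediate early (3.59e-05), Sertoli (0.00149), interferon (0.0164), elongating spermatid (0.0172) and p53 (0.0447) lists were higher. The axoneme and flagellum (3.44e-05, median -0.26, 54 of 60 members negative), ribosomal protein (0.00582) and glycolysis (0.0276) lists were lower. The adjusted p of these 8 lists ran from 0.270 to 0.840 with an estimated correlation. Without control meiotic replicate 2 the Sertoli (adjusted p = 0.875), ribosomal (0.853), elongating spermatid (0.237) and immediate early (0.0721) lists lost their call. Without control meiotic replicate 1 the interferon (0.294), p53 (0.191), glycolysis (0.178) and axoneme (0.0915) lists did. Leaving out cKO meiotic replicate 1 ended the calls of the Sertoli (0.183), glycolysis (0.0866), p53 (0.0523) and ribosomal lists (0.398, with the direction turned). Leaving out cKO meiotic replicate 2 ended those of the elongating spermatid and interferon (0.316 each) and p53 (0.0805) lists. Spike-in scaling ended those of the glycolysis (0.287) and p53 (0.0979) lists, and leaving out mature sperm that of the interferon list (0.0604). The replicate block ended that of the p53 list (0.0604) and added the protamine list (0.0429, higher). No single gene passed: edgeR's test gave 0 genes, with 593 at unadjusted p below 0.05, while DESeq2 gave 27 and limma-voom 2. The smallest p in either direction belonged to Hsd3b1 and to Dhx58 (-1.48, SE 0.26), each with an adjusted p of 0.315. Once the replicate number was a block, 36 genes passed (34 higher, 2 lower), among them Hsd3b1 (adjusted p = 0.00410) and Dhx58 (0.0112).

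In round spermatids the immediate early genes were higher as a set in Gcn5 cKO libraries (camera, adjusted p = 7.65e-09, 0.178 with an estimated correlation, median 1.61). When adjusted over the list alone 12 of its 24 members were higher, among them the transcription factors Egr2 (3.06, SE 0.70), Fosl2 (1.86, SE 0.46) and Jun (1.65, SE 0.43). Spermatogonial (1.64e-05), myoid and stromal (5.36e-05), Leydig (8.28e-05), endothelial, blood and immune (0.00312), p53 (0.00435) and interferon (0.0152) lists were higher as well. Markers of other cells that passed when adjusted over their list alone included Pdgfra (2.15, SE 0.36), the collagen chain Col1a2 (2.48, SE 0.53) and the invariant chain Cd74 of antigen-presenting cells (4.10, SE 0.93). Axoneme and flagellum (7.13e-08, median -0.32, 57 of 60 members negative), round spermatid (0.000236, median -0.27) and glycolysis (0.00664) lists were lower. With an estimated correlation the adjusted p of these other lists ran from 0.166 to 0.763. Without control round replicate 1 the interferon (adjusted p = 0.95), glycolysis (0.168) and round spermatid (0.0572) lists were not called, nor the interferon list without cKO round replicate 2 (0.0652) or glycolysis with spike-in scaling (0.102). For single genes edgeR's test gave 0, with 994 at unadjusted p below 0.05, while DESeq2 gave 67 and limma-voom 1. Dhx58 (-1.65, SE 0.27) and Pdgfra had the smallest adjusted p, 0.157. The replicate block gave 41 genes (34 higher, 7 lower), with Dhx58 and Pdgfra (adjusted p = 0.00322 each) and Col1a2 (0.0224) among them.

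In elongating spermatids Nptx2 was the 1 gene that rose (log2 change 3.77, SE 0.46, 13.6-fold, edgeR adjusted p = 0.00745), with 1552 genes at unadjusted p below 0.05; DESeq2 called 117 genes and limma-voom 1. The immediate early list was higher (camera, adjusted p = 3.83e-15; 0.146 with an estimated correlation), with a median log2 change of 2.09 and positive values in 24 of 24 members. Adjusted over the list alone 13 passed, among them Jun (2.41, SE 0.45) and Ier2 (2.85, SE 0.56). Its summed CPM was 451 and 783 in knockout and 235 and 254 in control libraries. Markers of other cell types were higher as sets: Leydig (1.57e-09, median 1.38, 8 of 22 adjusted over the list alone), endothelial, blood and immune (1.65e-08, median 1.56, 9 of 19), spermatogonia (7.82e-06, median 0.76), Sertoli (0.000367, median 0.51) and myoid and stroma (0.000809, median 0.62). The macrophage genes Lyz2 (3.89, SE 0.69) and C1qa (4.46, SE 0.96) and the cholesterol transporter gene Star (1.60, SE 0.42) were examples adjusted over the list alone. The p53 list was also higher (0.0388) and the axoneme and flagellum (8.28e-05, median -0.23) and round spermatid (0.0447) lists were lower. All these lists had an adjusted p from 0.146 to 0.790 with an estimated correlation. The round spermatid list lost its call when any 1 of 15 libraries was left out (adjusted p up to 0.306, without control elongating replicate 1) or with spike-in scaling (0.898). The p53 list lost its call without control elongating replicate 1 (0.228), and the axoneme list with spike-in scaling (0.247). Nptx2 lost its call without control elongating replicate 2 (adjusted p = 0.301) or cKO elongating replicate 2 (0.0962). Its contrast called 236 genes without control elongating replicate 1 and 10 without cKO elongating replicate 1. The replicate block gave 218 genes (121 higher, 97 lower), with Lyz2 (adjusted p = 0.00245) and Jun (0.00106) among them, and added the interferon (0.0186) and proteasome (0.04995) lists, both higher. With spike-in scaling, which moved the median of all genes in this contrast to 0.68, 63 genes passed (20 higher, 43 lower).

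In mature sperm the calcium release channel gene Ryr1 was the 1 gene that rose (log2 change 3.16, SE 0.44, 8.92-fold, edgeR adjusted p = 0.0360), with 2352 genes at unadjusted p below 0.05; DESeq2 called 187 genes and limma-voom 0. Axoneme and flagellum genes were higher as a set in Gcn5 cKO sperm (camera, adjusted p = 2.16e-06; 0.402 with an estimated correlation; median 0.51, 48 of 60 members positive), with Cfap43 (1.11, SE 0.27) higher when adjusted over the list alone. Myoid and stromal (3.02e-05, median 1.24, or 0.96 with genes without a count in a group at their bound), elongating spermatid (0.00294), round spermatid (0.00581) and epididymal epithelium (0.0388) lists were higher too. The actin-binding Cald1 (2.48, SE 0.76) and the receptor kinase Ros1 of the epididymis (2.24, SE 0.72) were examples adjusted over the list alone. The summed CPM of the epididymal list was 2823 and 1351 in knockout and 998 and 1771 in control sperm. The immediate early list was lower (0.000271, median -0.67), with Ier2 at -1.54 (SE 0.55) and Jun at -1.27 (SE 0.48). With an estimated correlation the adjusted p of these lists ran from 0.284 to 0.801. Ryr1 lost its call with RLE factors (adjusted p = 0.0558), spike-in scaling (0.312) or limma-voom (0.196), and when any 1 of 12 libraries was left out, all but those of control round and elongating spermatids (up to 0.0978, without cKO sperm replicate 1). Without cKO sperm replicate 1 the myoid (adjusted p = 0.82) and axoneme (0.185) lists lost their call, and the round spermatid (0.859), elongating spermatid (0.90) and epididymal (0.25) lists also turned direction. Without control sperm replicate 2 the round spermatid (0.792) and elongating spermatid (0.60) lists lost theirs. The count of genes was 19 without control sperm replicate 1, 16 without either control elongating library, 9 with upper-quartile factors and 28 with library size alone. It was 83 with the replicate block (59 higher, 24 lower), which also added the SAGA and ATAC list (0.0429, lower) and the ribosomal list (0.0456, higher).

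Whether the genotype effect differed between stages was tested as an interaction. No gene passed (edgeR's test gave 0, with 1096 at unadjusted p below 0.05; DESeq2 gave 94 and limma-voom 0). The smallest p-values belonged to the immediate early genes Jun and Ier2, followed by Polr1b, Stard6, Hexim1, Cfap157, Ttc39d, Thsd7a, Ugp2, Zfp184, Ppp1r15a and Ryr1, each with an adjusted p of 0.689. Jun had log2 changes of 1.65 in round spermatids, 2.41 in elongating spermatids and -1.27 in sperm. Without control elongating replicate 1 the interaction test called 27 genes, and with the replicate number as a block 6, or 8 with the block nested in genotype.

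FPKM values adjusted to spike-in RNA by the authors were used to ask whether the overall RNA level differed, which the count scaling removes. Whether the adjustment follows RNA output was not tested. The median over 21895 genes of log2(FPKM + 1) was 0.10 higher in Gcn5 cKO libraries on average over the stages (exact permutation test within stages, two-sided, p = 0.0154; smallest possible p 0.00154). The difference was 0.14 in meiotic cells, 0.09 in round spermatids, 0.16 in elongating spermatids and 0.02 in sperm. Within replicate numbers 1 and 2 it was -0.01 and 0.18 in round spermatids and 0.07 and -0.02 in sperm, so that its sign turned in these stages, and it was positive in both numbers in the other stages. With a pseudocount of 0.1 in place of 1 the average difference was 0.36 (exact permutation p = 0.0278), so its size depends on that choice. The call was lost when genes needed an FPKM of at least 1 in 2 libraries (difference 0.18, exact permutation p = 0.184) and for summed FPKM (0.29, exact permutation p = 0.403). Within replicate number 1 the difference was 0.11 and within replicate number 2 it was 0.10, where the smallest possible exact p of 0.125 is above the threshold (p = 0.25 each).

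**Figure D4:**
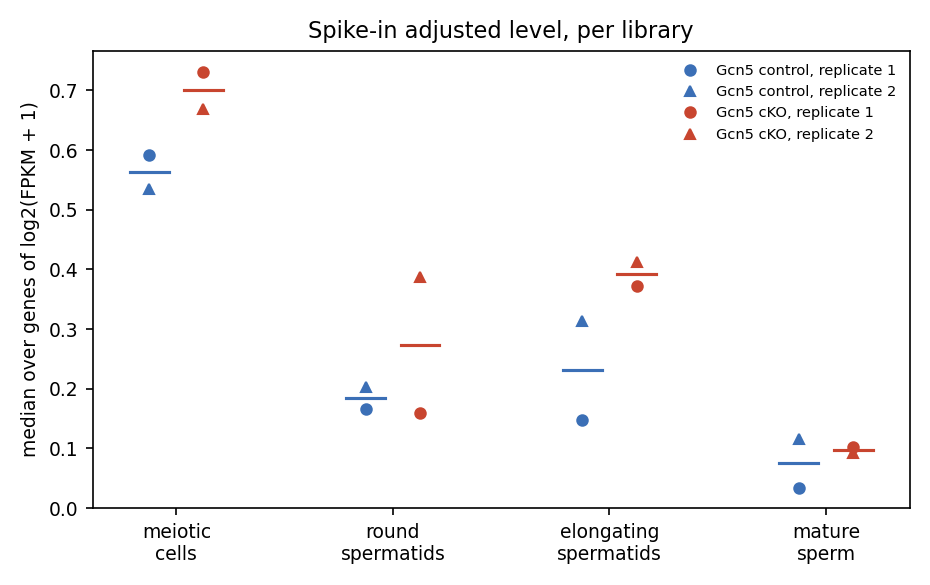
Median over genes of log2(FPKM + 1), adjusted to spike-ins by the authors (vertical axis), for each Gcn5 control and cKO library by stage (horizontal axis); points are libraries and bars are means of 2. Cells of the 2 genotypes differed by 0.14 in meiotic cells and 0.02 in sperm, where the medians were only 0.03 to 0.12. In log2 of summed FPKM the differences were 0.02 in meiotic cells and 0.33 in sperm, so the order of the stages depends on the measure.

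The control libraries gave the course of RNA levels over the fractions and sperm. Marker lists of other cells, such as Sertoli and Leydig cells and epididymal epithelium, also changed between them. Changes in germ cells and in the content of other cells were not told apart in these steps. Between meiotic cells and round spermatids 3848 genes rose and 4441 fell out of 17765 (edgeR, adjusted p below 0.05). Genes of the elongating spermatid list rose in 36 of 45 cases and none fell (camera, adjusted p = 2.97e-16; 0.306 with an estimated correlation), for example Akap4, the main scaffold of the fibrous sheath of the tail (log2 change 4.08, SE 0.34), and Odf1 of the outer dense fibres (3.76, SE 0.35). Of the round spermatid list 28 of 45 rose and 3 fell (1.46e-08), with the kinase Tssk3 (3.99, SE 0.38) and the acrosomal Acrv1 (3.83, SE 0.36). Of the protamine and transition list 11 of 15 rose and 2 fell (0.000162), with Prm2 at 4.31 (SE 0.44). Falling were 16 of 25 piRNA pathway genes against 1 that rose (0.000127; Piwil1 -4.17, SE 0.39) and 23 of 28 Sertoli genes against 2 (0.000222). So were 18 of 22 Leydig genes against 2 (0.000164; Hsd3b1 -5.64, SE 0.61) and 19 of 44 meiotic prophase genes against 7 (0.0237). Glycolysis genes were higher (10 rose, 2 fell; 0.00749) and proteasome genes lower (1 rose, 11 fell; 0.0210). Adjusted over the list alone the counts were 11 and 2 for glycolysis, 3 and 23 for Sertoli, 2 and 19 for Leydig and 1 and 8 for proteasome genes, and those over all genes for the other lists. With an estimated correlation the adjusted p of these lists ran from 0.306 to 0.57. Without mature sperm meiotic prophase (0.0743) and proteasome (0.0521) were not called, nor glycolysis with spike-in scaling (0.0501). By size, the leading rises were Cyp2a12 (5.10, SE 0.65, 34.3-fold), Frem3 (5.02, SE 0.76), A2m (4.99, SE 0.82), Gsdmd (4.96, SE 0.69), Slc17a6 (4.72, SE 0.59) and Igf1 (4.70, SE 0.58). The leading falls were the testis linker histone Hist1h1t (-6.23, SE 0.47, 75.1-fold), Pou5f2 (-5.65, SE 0.49), Hsd3b6 (-5.50, SE 0.71), Alyref2 (-5.41, SE 0.76), Bhmt (-5.06, SE 0.63) and Sap30 (-4.95, SE 0.50). With spike-in scaling the median of all genes in this step was -2.08 and 1035 genes rose while 9642 fell; with RLE factors 4136 rose and 3685 fell.

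Between round and elongating spermatids 2563 genes rose and 3084 fell in controls (edgeR). In the elongating spermatid list 30 of 45 rose and 1 fell (camera, adjusted p = 1.17e-15; 0.306 with an estimated correlation), among them Odf1 (3.55, SE 0.34) and Cabs1 (3.84, SE 0.39). In the protamine and transition list 8 of 15 rose and none fell (0.000210), with Prm2 (3.81, SE 0.43) and Tnp1 (2.89, SE 0.48). In the glycolysis list 11 of 19 rose and 5 fell (0.00807), with Tpi1 (2.49, SE 0.30). Sertoli cell genes rose in 24 of 28 cases and 1 fell (1.90e-11), for example the tight junction gene Cldn11 (5.14, SE 0.43). Leydig (10 rose, 1 fell; 0.000402), endothelial, blood and immune (6 rose; 0.00867), epididymal (7 rose, 3 fell; 0.0175), interferon (6 rose, 1 fell; 0.0283) and myoid (6 rose, 1 fell; 0.0413) lists were higher. The axoneme and flagellum list (3 rose, 29 fell; 1.03e-07), the round spermatid list (6 rose, 28 fell; 0.000440), meiotic prophase (2 rose, 11 fell; 0.0232) and proteasome (3 rose, 13 fell; 0.0313) were lower, and ribosomal protein genes higher (14 rose, 3 fell; 0.0175). Adjusted over the list alone the counts of rises and falls were 10 and 1 for protamines, 7 and 28 for round spermatid, 31 and 1 for elongating spermatid, 3 and 38 for axoneme, 12 and 1 for Leydig, 8 and 3 for epididymal, 9 and 2 for ribosomal and 5 and 1 for interferon genes, and those over all genes for the other lists. With an estimated correlation the adjusted p of these lists ran from 0.306 to 0.735. Calls ended without control elongating replicate 2 for interferon (0.294), myoid (0.188, and without 5 other libraries), epididymal (0.0682) and proteasome (0.0542), and without control elongating replicate 1 for ribosomal (0.31). They also ended without control round replicate 1 for interferon (0.262) and ribosomal (0.076), and without control round replicate 2 for meiotic prophase (0.0886) and proteasome (0.075). Without mature sperm meiotic prophase (0.0766), epididymal (0.0746) and interferon (0.169) were not called. With spike-in scaling myoid and ribosomal (0.0501 each) and proteasome (0.0601) were not. By size, Zic1 was at least 84.8-fold higher (0 counts in round spermatids), Rgs7bp rose by 7.36 (SE 1.58), Gda by 6.56 (SE 1.08), Dsg2 by 6.50 (SE 1.18), Mlph by 5.86 (SE 0.83) and Slc24a3 by 5.63 (SE 0.69). Among lower genes, Usp11 (-3.09, SE 0.48), Prr27 (-2.88, SE 0.67), Rhox11 (-2.83, SE 0.53), Speer4a (-2.75, SE 0.58) and Acot8 (-2.73, SE 0.49) led the falls. Without control elongating replicate 2 Rgs7bp (adjusted p = 0.658), Dsg2 (0.405) and Zic1 (0.245) lost their call, without control round replicate 1 Prr27 (0.0798), and with spike-in scaling Usp11 (0.0507), Acot8 (0.0544), Rhox11 (0.0876) and Speer4a (0.0966). The direction of the set depended on the scaling: RLE gave 3442 higher and 1627 lower, upper-quartile 3594 and 1352, library size alone 1532 and 5871, and spike-in scaling 1071 and 2. Leaving out control round replicate 1 (2900 genes), control elongating replicate 1 (2972) or control round replicate 2 (3178) lowered the count by over 1.5 times.

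Between elongating spermatids and sperm 3306 genes rose and 5198 fell in controls (edgeR). Spermatid genes fell, with 41 of 45 of the elongating spermatid list lower and none higher (camera, adjusted p = 3.45e-20; 0.306 with an estimated correlation), and 41 of 45 of the round spermatid list lower and 1 higher (1.62e-10). Falling too were 17 of 19 glycolysis genes (5.19e-09) and 11 of 15 protamine and transition genes (8.82e-05; Tnp1 -5.86, SE 0.55), with 1 that rose. The same held for 36 of 60 axoneme genes (2.85e-05), 54 of 84 ribosomal protein genes (0.000222), 17 of 25 piRNA genes (0.000647), 25 of 44 meiotic prophase genes (0.00577) and 14 of 28 Sertoli genes (0.0232). Akap4 fell by 5.56 (SE 0.37) and the testis lactate dehydrogenase Ldhc by 3.99 (SE 0.34). Higher were epididymal epithelium (15 of 31 rose, 3 fell; 0.000311), immediate early (13 of 24 rose, 2 fell; 0.00749), interferon (6 of 27; 0.00749), p53 (12 of 37 rose, 1 fell; 0.00801) and deacetylase genes (6 of 18 rose, 1 fell; 0.0232), for example the cadherin Cdh1 (5.27, SE 0.57) and Hdac6 (5.24, SE 0.36). Adjusted over the list alone the counts of rises and falls were 2 and 37 for axoneme, 1 and 18 for piRNA, 2 and 14 for Sertoli, 7 and 54 for ribosomal, 11 and 1 for p53 and 5 and 0 for interferon genes, and those over all genes for the other lists. With an estimated correlation the adjusted p of these lists ran from 0.306 to 0.584. The Sertoli call ended without control elongating replicate 1 (0.0513) or control sperm replicate 2 (0.0585), interferon without control sperm replicate 2 (0.0576) and deacetylases without control sperm replicate 1 (0.101). Many of the leading genes had no count in the other stage, so their folds are bounds against 3 counts over the group. The keratin Krt18 was at least 164-fold higher in sperm, Ltf, lactoferrin, at least 135-fold, Rab44 at least 137-fold, Mapk13 at least 114-fold and the epididymal Defb43 at least 54.7-fold. Prdx4 was at least 40.6-fold lower, Izumo2, an egg-binding family member, at least 33.7-fold, Cdkn1c at least 24.8-fold and Txndc8 at least 21.0-fold. Library size alone gave 5971 higher and 2592 lower genes, upper-quartile factors 4264 and 4170, and spike-in scaling 586 and 9235 with a median of all genes of -2.55.

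SV129E and Gcn5 control libraries were compared with stage as a term, with 1 SV129E library per stage. Of 18011 genes, 1773 were higher and 1314 lower in SV129E (edgeR). Higher were the mitochondrial leucyl-tRNA synthetase Lars2 (log2 change 6.82, SE 1.16), Bfsp1 (6.39, SE 0.41, 83.9-fold), the ribosomal protein gene Rpl38 (4.04, SE 0.30), Slc26a10 (4.67, SE 0.64) and Cpne7 (4.64, SE 0.75). These were followed by Ptpro (4.14, SE 0.56), Dnah11 (4.08, SE 0.34), Nalcn (3.68, SE 0.32), Col22a1 (3.61, SE 0.37), Polr2i (3.59, SE 0.28) and Cdh6 (3.37, SE 0.79), which lost its call without the SV129E round (adjusted p = 0.113) or meiotic library (0.0834). Within SV129E the levels of Lars2 ranked as those of the ribosomal RNA precursor Rn45s, with Lars2 at 1241, 656, 22.4 and 2066 CPM in the order of the stages and Rn45s at 19345, 9656, 451 and 176390 CPM. In the controls Lars2 was at 272 and 162 CPM in sperm, the stage where Rn45s was highest, and at most 15.1 CPM elsewhere. Several genes with counts in controls had no count in any SV129E library. The Y-linked Ssty1 was at least 2857-fold lower, Tagap at least 2524-fold, Tsnax at least 2047-fold, and the cholesterol synthesis gene Hmgcs1 at least 1388-fold. The Y-linked Uba1y was at least 962-fold, Smok3b at least 645-fold and Klrb1 at least 239-fold. Pirt was at least 384-fold lower, but it was at 0 CPM in the replicate 1 library of every control group and at 206 CPM in control elongating replicate 2. It was not called without 4 single libraries (adjusted p up to 0.198), without mature sperm (0.0602) or with the replicate block (1.00). Fam205a2 (-13.00, SE 0.56), the histone gene Hist1h2an (-10.50, SE 0.48), the Y-linked Sly (-10.18, SE 0.60) and Zfp131 (-10.07, SE 0.47) were also lower. Many of these belong to families of near-identical copies, for which counts are uncertain. The share of counts assigned to no gene was 0.00653 to 0.0186% in SV129E and 1.37 to 15.96% in the Gcn5 libraries. RLE factors gave 1261 higher and 1590 lower genes, library size alone 1156 and 1390, and spike-in scaling 371 and 610. The count was 1896, 1486 and 1451 without the SV129E meiotic, round and elongating library.

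The stage course of the backgrounds was compared across genes, which are not independent replicates. Log2 changes in SV129E and control correlated with Pearson's r of 0.907 and Spearman's rho of 0.889 from meiotic cells to round spermatids, 0.771 and 0.748 from round to elongating spermatids, and 0.814 and 0.796 from elongating spermatids to sperm, over 18972 genes. Among genes over 2-fold changed in control, 97.1, 89.0 and 89.0% had the same sign in SV129E. With spike-in adjusted FPKM the 3 values of r were 0.853, 0.577 and 0.944, and 93.4, 64.0 and 98.3% of the genes over 2-fold changed in control had the same sign.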

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

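The test in this part, of whether the genotype effect of each gene list in mature sperm differed from its mean in the 3 other stages, was chosen after the data were seen, as were its repeats with single libraries left out. Camera with the preset correlation called 10 lists, and none with an estimated correlation. Immediate early genes had a median log2 change of -0.67 in sperm against 0.61, 1.61 and 2.09 in meiotic cells, round and elongating spermatids (adjusted p = 1.38e-11; 0.141 with an estimated correlation). Axoneme and flagellum genes stood at 0.51 in sperm against -0.26, -0.32 and -0.23 (adjusted p = 1.99e-11; 0.188 with an estimated correlation). Leydig genes stood at 0.09 in sperm, where 8 of 22 had no count in a group, against 1.44, 0.90 and 1.38 (adjusted p = 6.73e-05; 0.188 with an estimated correlation). With such genes at their bound its medians were 0 in sperm and 0.80 in round spermatids. These 3 lists kept their call when any 1 of the 16 libraries was left out.

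The other 7 calls each ended without cKO sperm replicate 1, or turned direction. Round spermatid genes were at 0.33 in sperm against -0.10, -0.27 and -0.16 (adjusted p = 0.000209; 0.458 with an estimated correlation; 0.651 without cKO sperm replicate 1 and 0.301 without control sperm replicate 2), and elongating spermatid genes at 0.30 against 0.16, -0.08 and -0.01 (0.0281; 0.75 with an estimated correlation; 0.759 with the direction turned, and up to 0.751 without 5 other libraries). Spermatogonial genes were at -0.03 in sperm, or 0 with genes without a count in a group at their bound, against 0.54, 0.79 and 0.76 (0.00808; 0.458 with an estimated correlation; 0.136 without cKO sperm replicate 1, and 0.138 without control sperm replicate 1). Myoid and stromal genes were at 1.24 in sperm, or 0.96 with genes without a count in a group at their bound, against 0.08, 0.76 and 0.62 (0.0338; 0.644 with an estimated correlation; 0.506 with the direction turned, and up to 0.666 without 7 other libraries; 0.0693 with the replicate number as a block). Epididymal genes were at 0.18 against 0, 0 and -0.28, the last of which was 0 with 9 of 31 genes at their bound (0.0310; 0.612 with an estimated correlation; 0.506 with the direction turned). Ribosomal protein genes were at 0.26 against -0.17, -0.11 and 0.06 (0.0310; 0.797 with an estimated correlation; called in the other direction, 0.0426, without cKO sperm replicate 1, and up to 0.13 without 6 other libraries). Genes of the p53 list were at -0.15 against 0.16, 0.38 and 0.66 (0.0396; 0.188 with an estimated correlation; 0.149, and up to 0.41 without 7 other libraries; 0.0693 with the replicate number as a block).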

How the results depend on the processing

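Alternatives chosen after the data were seen were those without the shallowest (cKO sperm replicate 2) and the most divergent (control elongating replicate 2) library, the parts of cKO elongating replicate 1, replicate numbers alone, the pooled column read as a mean of 3, lists without sperm, with the replicate block or without single libraries, stage agreement without a replicate, and the adjusted level over pairs. Of the values for 193 named gene results, 5280 kept their side of the threshold and direction, 386 lost a call, 164 gained one, 73 moved and 0 turned; of those for 184 list results 3365, 200, 66, 175 and 12. The cause was not tested unless given.

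For the average, sperm, and elongating counts of 109, 1 and 1, upper-quartile factors gave 271, 9 and 1, library size alone 349, 28 and 1, and spike-in scaling 310, 0 and 63. RLE factors gave 0 in sperm, and spike-in scaling 1073 for elongating against round control cells and 981 for SV129E. Without a filter the counts were 48 meiotic, 55 round, 403 elongating, 226 sperm, 677 average and 280 interaction, and with at least 5 CPM 4 in sperm. DESeq2 gave 27, 67, 117, 187, 520 and 94 in the same order, and limma-voom 2 meiotic, 1 round, 0 sperm and 46 average. With only the 2 groups compared, a fit with fewer residual degrees of freedom, elongating and sperm gave 0, elongating against round 3371 and sperm against elongating 5435. Without sperm the average gave 708, and the stage lists called fell from 37 to 18 since 14 belonged to the missing contrast and 5 ended in the others. Limma-trend on adjusted FPKM gave 55 meiotic, 426 elongating and 226 average. Without the shallowest and most divergent library elongating gave 0, sperm 102 and average 207. In that setting the protamine, elongating spermatid and ribosomal lists turned direction in elongating spermatids, at unadjusted camera values of p in limma of 0.00206, 4.58e-07 and 0.0133. The low-weight part of cKO elongating replicate 1 gave 0 in sperm, the high-weight part 66 in the average.

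The groups share 2 replicate numbers, which nothing in the labels ties to a litter or day. Differences between replicates correlated across genotypes at 0.508, 0.517, 0.312 and 0.103 in the 4 stages, so same-numbered libraries moved together in meiotic cells and spermatids and weakly in sperm. With a replicate block the counts were 36 meiotic, 41 round, 218 elongating, 83 sperm, 599 average and 6 interaction (8 nested in genotype), with 48 genotype lists called against 45. The block added calls of 37 named genes and 5 lists, ended those of Pirt in SV129E and of the p53 list in meiotic cells and the average, and changed no other call of these.

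The call of the adjusted level difference of 0.10 was lost with FPKM of at least 1 (difference 0.177, exact permutation p = 0.184). It was also lost for summed FPKM (difference 0.286, exact permutation p = 0.403). With an estimated correlation 1 genotype list and 0 stage lists were called. The stage agreement moved to 0.930 and 0.862 with at least 5 CPM (round against meiotic, sperm against elongating) and to 0.853, 0.577 and 0.944 with FPKM.

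Leaving out single libraries gave ranges of 0 to 0 for meiotic and round, 0 to 236 elongating, 0 to 19 sperm, 20 to 205 average and 0 to 27 interaction. The ranges were 5964 to 9085, 2900 to 6544 and 7008 to 8684 for the control stage steps, 1451 to 3685 for SV129E, and 38 to 48 genotype and 33 to 39 stage lists. Leaving out a whole replicate number, not a single library, gave 0.0985 to 0.107 for the adjusted level. For stage agreement, leaving out a control replicate number gave 0.875 to 0.906, 0.604 to 0.785 and 0.724 to 0.749. The unadjusted camera p of lists that turned direction ranged from 6.08e-12 to 0.801 (ribosomal, meiotic), 0.00906 to 0.997 (proteasome, meiotic), 9.30e-05 to 0.870 (protamine, elongating), 5.10e-08 to 0.896 (elongating spermatid, elongating), 0.0107 to 0.600 (ribosomal, elongating), 3.85e-07 to 0.845 (elongating spermatid, sperm), 6.34e-07 to 0.778 (round spermatid, sperm), 2.90e-07 to 0.142 (epididymal, sperm) and 1.47e-06 to 0.0769 (ribosomal, sperm). Among the genotype contrasts recovery was lowest in sperm, where 4-fold changes were recovered in 11.1% of simulated genes. There 3 counts stood for 13.6 CPM in the shallowest library. Sperm replicates also correlated least (Pearson's r 0.612 in controls and 0.748 in knockouts), and depth and spread were not told apart. These values cover the 3840 and 4777 genes with enough counts in the pair, against 9420 to 13171 genes in the other stages. They are therefore not over the same genes.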

Other observations

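Tests chosen only after the result was seen were those of the X chromosome as a whole, of somatic cells in the fractions, of shared copies in SV129E, and of Kat2a reads and a strain segment at Dhx58. The others were written before their result was seen.

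Sex-linked genes were higher in Gcn5 cKO libraries in meiotic cells and spermatids. In sperm the median X-linked change from the control mean, less the autosomal one, was 0.38 in cKO replicate 1 and 0 in replicate 2. For Y-linked genes in sperm it was 0.84 and 1.10. The median log2 change in the average was 0.63 for X-linked (95% bootstrap interval 0.59 to 0.67, 85.2% of genes positive) and 1.06 for Y-linked genes against 0.00 for autosomal genes. The X against autosome difference passed an exact permutation test within stages (p = 0.00154), and without sperm, where the median of 1 shallow library is not informative (exact permutation p = 0.00926). Both take the stages as separate, which shared preparations would not be. The tables argue against spermatids in the knockout meiotic fraction, since 1793 autosomal genes matched on stage profile and level moved by 0.11 (0.07 to 0.15) against 0.71 for the X. In the round spermatid contrast 260 sex-linked genes over 8-fold higher in round than meiotic control cells moved by 0.58 (0.54 to 0.61). The other 505 moved by 0.81. These values argue against somatic cells as the whole cause. A part from somatic cells stays open, since the Leydig, myoid and immune lists were also higher in that contrast. Reads shared between copies are argued against for the X. There 454 X-linked genes with little shared sequence moved by 0.61 (0.56 to 0.65) in the average. Y-linked genes were not tested for shared reads. Other tests, filters and left-out libraries kept the X against autosome difference between 0.54 and 0.73, and it was 0.07 on the compressed log2(FPKM + 1) scale. Other scalings shift X-linked and autosomal genes of a library alike, so they cannot test this difference. The strain origin of the X and Y chromosomes on this mixed background was not tested and stays open beside the genotype. Less complete silencing of the sex chromosomes in the knockout may be a candidate explanation, and no test here addressed it.

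Dhx58, the neighbour of Kat2a, fell from 123 ± 13.3 to 45.3 ± 5.23 CPM in meiotic cells, from 66.8 ± 1.26 to 21.3 ± 1.77 CPM in round spermatids and from 22.3 ± 1.11 to 12.6 ± 0.267 CPM in elongating spermatids (SD, n = 2 libraries per group). In sperm it was at 3.31 ± 0.366 and 2.87 ± 0.0811 CPM (SD, n = 2), from 1 to 6 counts per library, where a fall was not detectable. The fall was called in the average, and with the replicate block also in meiotic cells and round spermatids. Kat2a reads counted in Dhx58 are argued against by the size of the meiotic fall, 84.0 CPM when only the 16 Gcn5 libraries are scaled together, 3.80 times the whole control level of Kat2a on that scale. A strain segment around the floxed allele, shared with SV129E and lowering Dhx58, is argued against as the whole cause by its change of -0.026 (SE 0.23) in SV129E. That change joins stages of opposite sign. SV129E held less Dhx58 than the control mean in meiotic cells (96.8 CPM) and round spermatids (51.6 CPM). It held more in elongating spermatids (28.9 CPM) and sperm (5.42 CPM). A smaller part from such a segment stays open, with 1 SV129E library per stage. A region of lower expression is argued against by 0 of the 19 nearest tested genes being lower at unadjusted p below 0.05, while Stat5b (0.76, SE 0.25) and Stat3 (0.46, SE 0.17) lay higher at that level. Removal of a shared regulatory sequence by the deletion may remain as an explanation, as may a response to the loss of Gcn5, and neither was tested.

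In SV129E 379 genes were over 16-fold lower than in the Gcn5 controls. Of the 346 with a sequence value, 56.1% shared at least 50% of their sequence with another gene, against 4.33% of the other genes tested (Fisher's exact test, p = 3.60e-157; genes are not independent). Different treatment of reads with several matches in the counting of the backgrounds may therefore account for many of them. Whether the far smaller share of counts of no gene in SV129E has the same origin was not tested. Of the remaining 152 genes, 25% overlapped another gene in GENCODE M21 against 33.5% of other genes (Fisher's exact p = 0.0304). This cannot decide on a different set of gene models, since the annotation used for the counts is not given. Strain differences and differences in counting stay open for these 152 genes.

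Other splits of the libraries within stages showed whether chance can be excluded. For the 109 genes of the average, 5 of 100 splits out of 648 gave as many, so chance was not excluded. The 5 were the real split, drawn splits with 302, 208 and 183 genes, and the split by replicate number. That last split was put in rather than drawn, and the verdict depends on counting it. It gave the highest count, 1395 genes, which points to a structure of the samples. The count within replicate number 1 was 163 and within number 2 it was 108. With the replicate number as a block, added after the other splits were seen, 1 of 100 splits that part every pair (drawn from 128) gave as many as 599 genes, the real one. The highest other, in which 12 of the 16 libraries kept their genotype, gave 425, so chance was excluded for the blocked count if the stages are separate units. For the gene lists of the average, 11 were called when adjusted within that contrast alone (10 over all genotype contrasts), and 9 of 100 splits gave as many, with 12 in the highest other and a median of 7, so chance was not excluded. With the block 9 lists were called, and 21 of 100 splits that part every pair gave as many, with 12 in the highest other and a median of 6, so chance was not excluded there either. For SV129E, 1 of 81 splits gave as many as 3087 genes, the real one, with 510 in the highest other, so chance was excluded on the same condition. These splits exchange libraries in each stage on its own, while differences between replicates correlated across stages (0.510 between control meiotic cells and round spermatids). If the fractions of a replicate number share a preparation, 2 units per Gcn5 genotype and 1 of SV129E remain, and chance between preparations is not excluded.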
